A study of Mus musculus with 94 samples.

How the data were processed

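Poly(A) RNA was sequenced, per the labels as paired-end reads on an Illumina NovaSeq, from the epididymal (eWAT) and inguinal (iWAT) white adipose tissue of 47 male C57BL/6JBomTac mice. The 94 libraries form 8 groups in each tissue. Obese mice had eaten a high-fat diet for 18 weeks, regression mice had eaten it for 18 weeks and then a low-fat diet for 2, 6 or 12 weeks, and lean mice of the same age, on the low-fat diet throughout, were killed at each of the 4 times. The obese group had 5 mice and every other group 6. The labels call the libraries of a group biological replicates, and the mouse numbers in them pair the 2 depots of each mouse. Mice shared cages, and which mice did so is not given in the sources used here.

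The authors deposited whole-number counts per gene symbol for every library, with no normalization. The submitters' processing notes name STAR 2.4.1c, the genome build mm10, R 4.2.2 and DESeq2 1.38.3; the counting program, the annotation and the strand setting are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes could therefore not be told apart. A deposited table per tissue holds the authors' DESeq2 results at the 4 times. Per the file headers these are the mean of the normalised counts (a signal value), a log2 fold change, its standard error, a test score (the Wald statistic) and p-values. These tables served only to set the authors' calls beside the calls made here. Their sign was checked against the counts, and a positive value means higher in the obese or regression mice.

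Library totals ran from 1.32 to 25.9 M counts in eWAT and from 6.27 to 34.3 M in iWAT. Gene positions were taken from GENCODE M21, which uses mm10; of the 14658 symbols tested in either tissue, 14174 were found there exactly once. Before any averaging, replicates were compared by a chi-square test of their counts over genes with a summed count of at least 20. The lowest chi-square per degree of freedom was 3.63 in eWAT and 7.11 in iWAT, so no pair agreed within sampling noise, and each library counted as 1 replicate.

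Each tissue was fitted with edgeR 4.0.16 (R 4.3.3) over all 47 libraries, with TMM normalization, the default filter on low counts and the quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 14323 in eWAT and 13899 in iWAT. Unless another tool is named, every adjusted p of a gene comes from this two-sided test, and values after ± beside a log2 fold change are standard errors of the fit. Obese or regression mice were compared with the lean mice of the same time. The change of that difference between obesity and each later time, and the difference between lean mice at 12 weeks and at the obesity time, came from the same fit. No library is shared between the comparisons at different times. The difference between the tissues was fitted over all 94 libraries with mouse as a block, because both depots came from the same mice. Levels are given as CPM, counts scaled to a common library total, with the SD between mice, and log2 CPM used a prior count of 2.

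44 gene lists for pathways, cell types and other tissues were fixed with the comparisons before the data were examined. In each list the members called over all genes were counted, and again with the p-values adjusted over the list alone. Lists were tested with camera in limma 3.58.1, which sets a list against all other genes, with the correlation between genes estimated from the data. The same test with the preset correlation of 0.01 and fry, which asks whether a list moves one way without comparing it with other genes, were alternatives. The mean log2 CPM of a list per mouse was also compared between groups by an exact permutation test, two-sided, with Benjamini-Hochberg adjustment over 332 such tests; with 6 mice against 6 or 5 against 6 the smallest p it can give is 0.00216. This last test was added after the data were seen. It exchanges single mice and leaves aside which mice shared a cage.

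Named genes follow a rule fixed at the same time. It takes 30 marker genes of fat tissue, the 5 genes with the largest positive and the 5 with the largest negative log2 fold change per comparison among called genes with a mean of at least 5 CPM and a standard symbol, the leading 4 members of each list past its camera test, and the 10 strongest genes called in the same direction at all 4 times. Further list members named as examples, and the genes of comparisons with few calls, were chosen after their values were seen. Some genes that the rule or the lists hold are not reported here.

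Alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, its size factors in edgeR, no count filter, the replicate number as a block, the run of neighbouring mouse numbers in a group as a random block, the series of mouse numbers as a term or fitted apart (3693 to 3728 for replicates 4 to 6, 3744 to 3785 for replicates 1 to 3), a fit on the compared groups alone, and leaving out each library in turn. After the data had been seen, fits were added that hold signals of other tissues as terms or leave out libraries. The signals were the mean log2 CPM of 9 markers of efferent duct epithelium and of 4 markers of vas deferens epithelium in eWAT, and of the fixed skeletal muscle and B cell lists in iWAT. Same-numbered libraries of different groups did not deviate together in every pair, so the replicate number was not treated as a pairing.

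The procedure was tested on simulated counts drawn from the means, spreads and library sizes of the real libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For eWAT at 12 weeks, run on 14218 genes, 46.3% of 1.5-fold, 76.1% of 2-fold and 92.4% of 4-fold changes were recovered. For iWAT at 12 weeks, run on 13780 genes, the shares were 52.2%, 80.6% and 95.5%. The difference between the tissues at 12 weeks, fitted here on the 12-week libraries alone and run on 13750 genes, recovered 8.96%, 50.7% and 77.3%. Before the changes a gene had the same mean in all simulated libraries, counts were independent between genes, and weakly expressed genes were not changed. The shares thus leave out differences between depots, correlation between genes and shared signals of other tissues. In these simulations 7, 7 and 2 unchanged genes were called. Counts of calls were also compared with those of other splits of the same libraries, drawn with a fixed seed. Counts written as 4.3e+02 are rounded to 2 digits.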

Results

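RNA from epididymal (eWAT) and inguinal (iWAT) white fat of 47 male mice was compared between obesity and its regression. The obese group held 5 mice after 18 weeks of high-fat diet; the groups returned to a low-fat diet for 2, 6 or 12 weeks held 6 mice each, and each time had its own group of 6 lean mice of the same age. Both depots came from each mouse, which gives 94 libraries. Total counts per library ran from 1.32 to 25.9 M in eWAT and from 6.27 to 34.3 M in iWAT. No difference in totals passed its test after adjustment over 8 comparisons. The 3 with an exact permutation p under 0.05 were in eWAT: obese mice 8.38 ± 0.85 against 10.14 ± 1.25 M (SD, exact permutation p = 0.0281, adjusted p = 0.0867), 2 weeks 6.67 ± 3.49 against 11.63 ± 3.50 M (exact permutation p = 0.0325, adjusted p = 0.0867) and 6 weeks 11.26 ± 3.83 against 6.93 ± 0.54 M (exact permutation p = 0.00649, adjusted p = 0.0519). The questions were how far the fat of obese mice differed from that of lean mice, which differences were still found after 2, 6 and 12 weeks on the low-fat diet, and whether the depots differed in this. Gene positions refer to mm10.

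**Figure D1:**
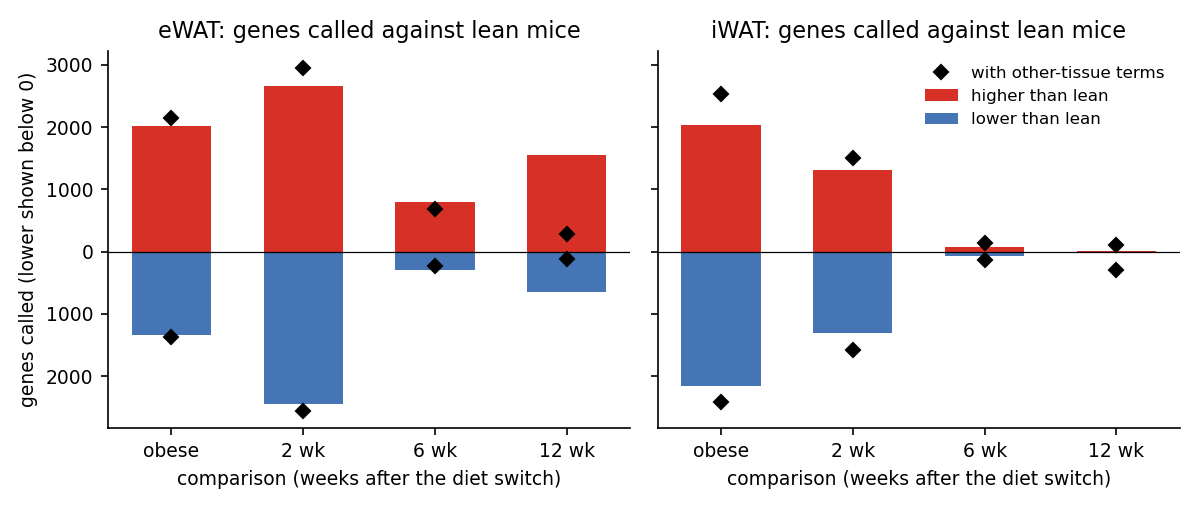
Number of genes called higher and lower in obese or regression mice than in lean mice of the same time (bars, number of genes), per tissue and time, with diamonds for the fit that holds other-tissue signals as terms. In eWAT at 12 weeks 1549 genes were higher and 646 lower, and 281 and 116 with the terms; in iWAT 3 were higher and 1 lower, and 112 and 295 with the terms.

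In the eWAT of obese mice, Elovl6 and Fasn were among the genes that fell and Lep, Trem2 and Col6a3 among those that rose. Lep, which encodes the adipocyte hormone leptin (chromosome 6, 29060220 to 29073877), was 4911 ± 1820 against 1068 ± 368 CPM (log2 fold change 2.20 ± 0.29, adjusted p = 1.98e-06; n = 5 and 6). Sfrp5, a secreted Wnt inhibitor, rose by 3.09 ± 0.46 and Mest by 1.31 ± 0.39; of the adipocyte enlargement genes 4 of 5 rose (5 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation). Elovl6, a fatty acid elongase (chromosome 3, 129532355 to 129638495), fell from 1213 to 68.0 CPM (-4.16 ± 0.60, adjusted p = 8.32e-06), beside Fasn (-2.64 ± 0.53), Acly (-3.14 ± 0.52) and Scd1 (-1.90 ± 0.39). The insulin-responsive glucose transporter Slc2a4 fell (-1.19), as did Pparg (-0.80) and Irs1 (-0.81). Of the macrophage genes, Cd68 rose by 2.89 ± 0.55 and Trem2, a lipid-sensing receptor (chromosome 17, 48346401 to 48354147), by 3.93 ± 0.76. The genes with the largest rise included Tm4sf19 (6.54), Mmp12 (6.38), Rgs1 (6.24) and Atp6v0d2 (5.67); those with the largest fall included H2-Q10 (-3.75), Cyp2f2 (-3.51) and Slc2a5 (-3.49). Obese replicate 4 held 53.8% of the group's CPM of Tm4sf19, 52.5% of Mmp12, 48.4% of Rgs1 and 51.6% of Atp6v0d2. Akr1b7 and Crisp1 were also called higher, with 99.3% and 99.2% of the group's CPM in obese replicate 5.

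Over all genes, 2013 were higher and 1333 lower in the eWAT of obese mice (3346 of 14323 tested). The count of eWAT obesity was 1722 without obese replicate 4, and 1513 and 607 in the mouse series of replicates 4 to 6 and 1 to 3 fitted apart. Among the lists, 26 of 26 respiratory chain subunits fell, for example Sdhb (-0.88) and Ndufa9 (-0.66), and 26 adjusted over the list alone; no call of the list was made with an estimated correlation (adjusted p = 0.122). In the tricarboxylic acid cycle 17 of 19 genes fell (18 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation), led by Pdha1 (-1.36). Of the genes of branched-chain amino acid breakdown 17 of 19 fell (19 adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), Bcat2 by -0.86. 15 of 20 de novo lipogenesis genes fell (17 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation). Of the macrophage genes 17 of 18 rose (17 adjusted over the list alone; adjusted p = 0.469 with an estimated correlation), of the extracellular matrix genes 18 of 22 (18; adjusted p = 0.122) and of the cell division genes 19 of 21 (20; adjusted p = 0.482), for example Col6a3 (1.65), Col1a1 (1.20), Mki67 (2.23) and Top2a (2.15). Pdk1 (-1.64) and Egln3 (-1.29), both targets of the hypoxia factor, fell while Hif1a itself rose (0.57). The hypoxia list went both ways, with 4 of 14 genes higher and 5 lower (4 and 5 adjusted over the list alone; adjusted p = 0.482 with an estimated correlation). The clock gene Nr1d1 fell (-0.97). The camera test called 0 of 42 lists with an estimated correlation, 22 with the preset correlation and fry called 18.

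In the iWAT of obese mice genes of lipid making, mitochondria and heat production were among those that fell. Slc2a5, a fructose transporter, fell from 63.0 ± 19.4 to 0.342 ± 0.639 CPM (-7.58 ± 0.82, adjusted p = 2.87e-08). Ucp1, which uncouples respiration to release heat (chromosome 8, 83290352 to 83298452), was 1.05 ± 1.86 against 53.8 ± 41.3 CPM (-5.76 ± 1.14, adjusted p = 0.000185). Elovl6 fell by 5.62 on the log2 scale, Aspg by 5.74, Sorcs2 by 5.22, Acly by 4.01 and Slc2a4 by 1.44. Lep (2.13), Sfrp5 (3.24) and Mest (2.99) rose. The largest rises included Sez6l (5.19), Tph2 (5.12), Itgad (5.06) and Slc5a7 (4.88). Cd68 rose by 1.29 ± 0.41 and Trem2 by 1.75 ± 0.66 (adjusted p = 0.0411).

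Over all genes, 2037 were higher and 2158 lower in the iWAT of obese mice (4195 of 13899 tested). For iWAT obesity the mouse series of replicates 4 to 6 and 1 to 3 gave 1327 and 2583. Of the lists, 18 of 19 de novo lipogenesis genes fell (18 adjusted over the list alone; adjusted p = 0.256 with an estimated correlation). So did 19 of 19 genes of the tricarboxylic acid cycle (19; adjusted p = 0.330), 25 of 26 respiratory chain subunits (26; adjusted p = 0.330) and 11 of 15 thermogenic genes (11; adjusted p = 0.330), for example Cidea (-3.52), Elovl3 (-4.56) and Pdha1 (-1.92). Of the extracellular matrix genes 20 of 22 rose (21 adjusted over the list alone; adjusted p = 0.330 with an estimated correlation), for example Fbn1 (1.63) and Sparc (0.99). Resident macrophage genes rose in 9 of 12 members (10 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation), among them F13a1 (1.18) and Lyve1 (1.07). With an estimated correlation camera called 0 of 41 lists, with the preset correlation 21, and fry called 23. The depots shared 1067 genes called higher (296.5 for independent lists) and 958 called lower (208.1). Both depots came from the same mice, which the values for independent lists leave aside.

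After 2 weeks on the low-fat diet the eWAT of regression mice had lost the rise of Lep, while Elovl6 and Fasn were lower and Gpnmb and Mmp12 higher. Lep was 1006 ± 273 against 1870 ± 563 CPM, a fall of 0.89 ± 0.27 (adjusted p = 0.00902; n = 6 and 6). Elovl6 (-4.37 ± 0.57), Acly (-3.42 ± 0.49) and Fasn (-3.23 ± 0.51) were lower. Of the de novo lipogenesis genes 16 of 20 fell (16 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation) and of the triglyceride synthesis genes 7 of 9 (7; adjusted p = 0.344), for example Mogat2 (-3.23), Agpat2 (-2.50) and Dgat2 (-1.96). Gpnmb was 891 against 19.1 CPM (5.54 ± 0.85, adjusted p = 7.92e-06) and Mmp12, an elastase of macrophages (chromosome 9, 7344381 to 7369499), 292 ± 152 against 1.33 ± 1.20 CPM (7.80 ± 1.08, adjusted p = 2.35e-06). Spp1 rose (3.44 ± 1.05, adjusted p = 0.00927) and Mmp3 by 3.99 ± 0.56. In eWAT Spp1 had no call in obesity (1.36 ± 0.99, adjusted p = 0.351), at 6 weeks (2.86 ± 1.07, adjusted p = 0.0894) or at 12 weeks (0.89 ± 0.95, adjusted p = 0.526). With duct and vas deferens signals as terms its adjusted p at these times was 0.0402, 0.0267 and 0.0917. The genes with the largest fall, Akr1b7, Crisp1, Serpina1f, Spink8 and Ptgs2, came from 1 lean library: Akr1b7 was 1320 CPM in lean replicate 2 and at most 0.198 CPM in the others.

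Over all genes, 2661 were higher and 2450 lower in eWAT at 2 weeks (5111). The mouse series of replicates 1 to 3 gave 2108 for eWAT 2 weeks. Of the macrophage genes 18 of 18 rose (18 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), of the lipid-associated macrophage genes 14 of 17 (14; adjusted p = 0.455) and of the lysosome genes 20 of 24 (21; adjusted p = 0.374), for example Ctsz (1.17) and Hexa (1.17). Cholesterol synthesis genes fell in 17 of 20 members (18 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), for example Insig1 (-2.44), Pmvk (-2.44) and Lss (-2.18). Of the unfolded protein response genes 11 of 17 rose (12 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), led by Sdf2l1 (1.62) and Creld2 (1.01). 0 of 42 lists were past camera with an estimated correlation, 22 with the preset correlation and 25 past fry. Of the 3346 genes called in obese mice, 1909 were called in the same direction at 2 weeks (1232 higher, 374 for independent lists; 677 lower, 228 for independent lists). The opposite direction was called for 81.

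In iWAT at 2 weeks de novo lipogenesis was the only list past its test in the fit over all libraries, and camera called 0 lists on the compared groups alone. 18 of 19 genes of it fell (18 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.0357; 25 lists with the preset correlation and 17 with fry). Elovl6 fell from 2881 ± 1740 to 60.6 ± 42.2 CPM (-5.57 ± 0.60, adjusted p = 9.94e-08), Acss2 by 3.77 ± 0.44 and Scd2 by 3.13 ± 0.38 on the log2 scale. Elovl3 (-7.31), Ucp1 (-5.19) and Slc2a5 (-5.07) were lower; lean replicate 3 held 60.3% of the lean group's CPM of Ucp1 and 46.4% of Elovl3. Thbs1, a matrix glycoprotein, rose from 16.6 ± 10.7 to 268 ± 113 CPM (4.01 ± 0.52, adjusted p = 9.75e-07), beside Ccl7 (2.87), Ccl2 (2.65), Mt2 (2.85) and Fosb (3.29). Cholesterol synthesis genes fell in 14 of 20 members (16 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation) and unfolded protein response genes rose in 11 of 17 (13; adjusted p = 0.0951). Lep had no call (0.12 ± 0.36, adjusted p = 0.850). 9 of 15 T cell genes were lower (15 adjusted over the list alone; adjusted p = 0.585 with an estimated correlation), Cd8a by 3.77; with muscle and lymph node signals as terms 1 of 15 was lower, and 3 of the 6 lean libraries held a B cell signal of at least 2 log2 CPM. Over all genes 1312 were higher and 1302 lower (2614). For iWAT 2 weeks the count was 1347 on the compared groups alone, 1219 with the run of mouse numbers as a random block and 700 in the mouse series of replicates 1 to 3. In all, 1278 of the 4195 genes called in obese mice were called in the same direction (531 higher, 192.3 for independent lists; 747 lower, 202.2 for independent lists).

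After 6 weeks Fasn and Elovl6 had no call in eWAT, while Mmp12, Trem2 and other macrophage genes were called higher. Fasn (-0.45 ± 0.47, adjusted p = 0.568), Elovl6 (-0.61 ± 0.49, adjusted p = 0.441), Lep (-0.09 ± 0.27) and Slc2a4 (-0.24 ± 0.23) were within their error or close to it. Mmp12 was 216 ± 228 against 0.594 ± 0.522 CPM (8.52 ± 1.23, adjusted p = 0.000245), and Trem2 (4.30 ± 0.78), Itgax (4.61 ± 0.83) and Cd68 (2.93 ± 0.55) were called higher. Regression replicate 6 held 49.1% of the group's CPM of Mmp12 (643 CPM, next 286), 52.9% of Itgax and 55.6% of Gpnmb. 15 of 18 macrophage genes rose (16 adjusted over the list alone; adjusted p = 0.478 with an estimated correlation), 11 of 17 lipid-associated macrophage genes (14; adjusted p = 0.478) and 2 of 20 de novo lipogenesis genes fell (2; adjusted p = 0.548). Akr1b7, with 2900 CPM in lean replicate 5 and at most 0.155 CPM in the other lean libraries, headed the genes that fell, beside Crisp1, Serpina1f, Spink8 and Defb42 from the same library. The count of eWAT 6 weeks was 178 without regression replicate 6, 583 without replicate 5, 664 without lean replicate 3 and 23 with the run of mouse numbers as a random block. In the mouse series of replicates 4 to 6 and 1 to 3 edgeR called 0 and 0 (2542 and 1908 at an unadjusted p under 0.05). Over all genes 796 were higher and 290 lower (1086). 673 of the obesity calls were found again (609 higher, 111.9 for independent lists; 64 lower, 27 for independent lists). The camera test called 0 of 42 lists with an estimated correlation, 22 with the preset correlation and fry called 4.

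In iWAT at 6 weeks 77 genes were higher and 67 lower (144). Left-out libraries gave 55 to 330 for iWAT 6 weeks, and the count was 31 with the run of mouse numbers as a random block, and 5 and 3 in the mouse series of replicates 4 to 6 and 1 to 3. Klf14, a transcription factor, rose from 8.14 ± 3.91 to 31.7 ± 12.1 CPM (1.98 ± 0.42, adjusted p = 0.00854), Mdk by 1.85 ± 0.34 and Map1a by 1.65 ± 0.30. Sorcs2, which had fallen in obese mice, was 19.3 ± 14.2 against 93.5 ± 35.4 CPM (-2.28 ± 0.38, adjusted p = 0.000873), and Kcng4 (-2.81), Slc9a2 (-2.42) and Tmem56 (-2.29) also fell. The hypoxia targets Pdk1 (-0.77 ± 0.20) and Egln3 (-1.27 ± 0.26) were lower, the 2 of 14 hypoxia genes called (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.83 with an estimated correlation). Tchh and Lor, genes of hair and skin, were called higher with 89.2% and 93.4% of the group's CPM in replicate 3 of the regression mice. Elovl6 had no call (-1.56 ± 0.50, adjusted p = 0.0991). 0 of 26 respiratory chain subunits were called over all genes and 23 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). With an estimated correlation camera called 0 of 41 lists, with the preset correlation 16, and fry called 0. Of the obesity calls 105 were found again (54 higher, 11.3 for independent lists; 51 lower, 10.4 for independent lists).

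After 12 weeks the eWAT of regression mice still held high mean levels of macrophage genes, though not in every mouse. The lowest regression library was under the highest lean library for Mmp12 (1.28 against 1.44 CPM), Itgax (2.35 against 3.54 CPM) and Gpnmb (20.8 against 24.1 CPM). Trem2 was 81.5 ± 65.1 against 4.93 ± 2.08 CPM (4.03 ± 0.75, adjusted p = 0.000812; n = 6 and 6), Gpnmb 422.5 ± 385 against 15.3 ± 6.41 CPM (4.78 ± 0.83, adjusted p = 0.000636), Itgax 75.7 ± 69.1 against 2.25 ± 1.16 CPM (5.08 ± 0.83, adjusted p = 0.000482) and Mmp12 235 ± 212 against 0.775 ± 0.574 CPM (8.20 ± 1.17, adjusted p = 0.000196). Cd68 (3.06 ± 0.55), Ctss (3.42 ± 0.57), Lyz2 (2.15 ± 0.38) and Saa3 (1.96 ± 0.42) were higher. The T cell genes Cd3d (3.06 ± 0.84) and Cd8a (2.55 ± 0.71), Nkg7 of cytotoxic cells (2.59 ± 0.62) and Foxp3 of regulatory T cells (1.93 ± 0.56) were called higher, as were Cma1 (1.67 ± 0.43) and Mcpt4 (1.53 ± 0.39) of mast cells. Fasn (-0.57 ± 0.47, adjusted p = 0.395), Elovl6 (adjusted p = 0.652), Slc2a4 (adjusted p = 0.329) and Lep (-0.23 ± 0.27, adjusted p = 0.556) had no call. The largest falls included Pdzk1ip1 (-2.51), Sec14l4 (-2.08), Adam11 (-1.99) and Cish (-1.97). The highest regression library held 10.2 CPM of Pdzk1ip1 (group mean 2.50), 15.8 of Sec14l4 (4.08) and 29.6 of Adam11 (9.73). The lowest lean library held 2.53, 5.34 and 12.6 CPM of these. Cish was 135 CPM in the highest lean library and 133 in the next (group mean 58.2). Values of these genes with duct signal as a term are not given here.

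Duct markers moved with these groups. All 6 lean eWAT libraries of 12 weeks held a signal of efferent duct epithelium of at least 2 log2 CPM (5.08 ± 1.17, SD), against 1 of 6 regression libraries (-0.30 ± 3.00, exact permutation p = 0.0108, adjusted p = 0.173 over 16 tests). Foxj1, a gene of ciliated cells, was 156 ± 83.1 against 40.2 ± 97.7 CPM. With the duct and vas deferens signals as terms 281 genes were higher and 116 lower, of which 246 and 88 were also called without the terms, where 1549 and 646 were called (2195). The count of eWAT 12 weeks was 4253 without regression replicate 3, 1395, 1280 and 1374 without replicates 2, 4 and 5 and 1403 without lean replicate 2, and 1 and 672 in the mouse series of replicates 4 to 6 and 1 to 3. The median log2 fold change of the higher genes moved from 0.86 to 0.70, with a median SE of 0.23 without and 0.25 with the terms, and that of the lower genes from -0.52 to -0.40 (SE 0.16 and 0.16). Trem2 (3.60 ± 0.90, adjusted p = 0.0393), Mmp12 (7.37 ± 1.35, adjusted p = 0.0227), Gpnmb (4.57 ± 0.95) and Cd68 (2.75 ± 0.63) were called with the terms, while Cd8a (1.79 ± 0.80, adjusted p = 0.155), Cd3e (1.21 ± 0.62, adjusted p = 0.215) and Foxp3 (1.73 ± 0.63, adjusted p = 0.0909) were not. Of the effector T cell and NK cell genes 8 of 12 were higher (10 adjusted over the list alone, 0 with the terms; adjusted p = 0.401 with an estimated correlation), and of the regulatory T cell genes 2 of 8 (2, 0 with the terms; adjusted p = 0.401). 17 of 18 macrophage genes rose (17 adjusted over the list alone, 15 with the terms; adjusted p = 0.401 with an estimated correlation) and so did 11 of 17 lipid-associated macrophage genes (12, 10 with the terms; adjusted p = 0.401). 12 of 15 T cell genes were higher (14 adjusted over the list alone, 0 with the terms; adjusted p = 0.401 with an estimated correlation), as were 13 of 24 lysosome genes (17, 1 with the terms; adjusted p = 0.401) and 8 of 10 genes of MHC class II presentation (9, 2 with the terms; adjusted p = 0.401). 0 of 42 lists were past camera with an estimated correlation, 26 with the preset correlation and 23 past fry. Of the obesity calls 1102 were found again without the terms (918 higher, 217.7 for independent lists; 184 lower, 60.1 for independent lists). With the terms far fewer were found again, and that count is given in the part on processing.

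**Figure D2:**
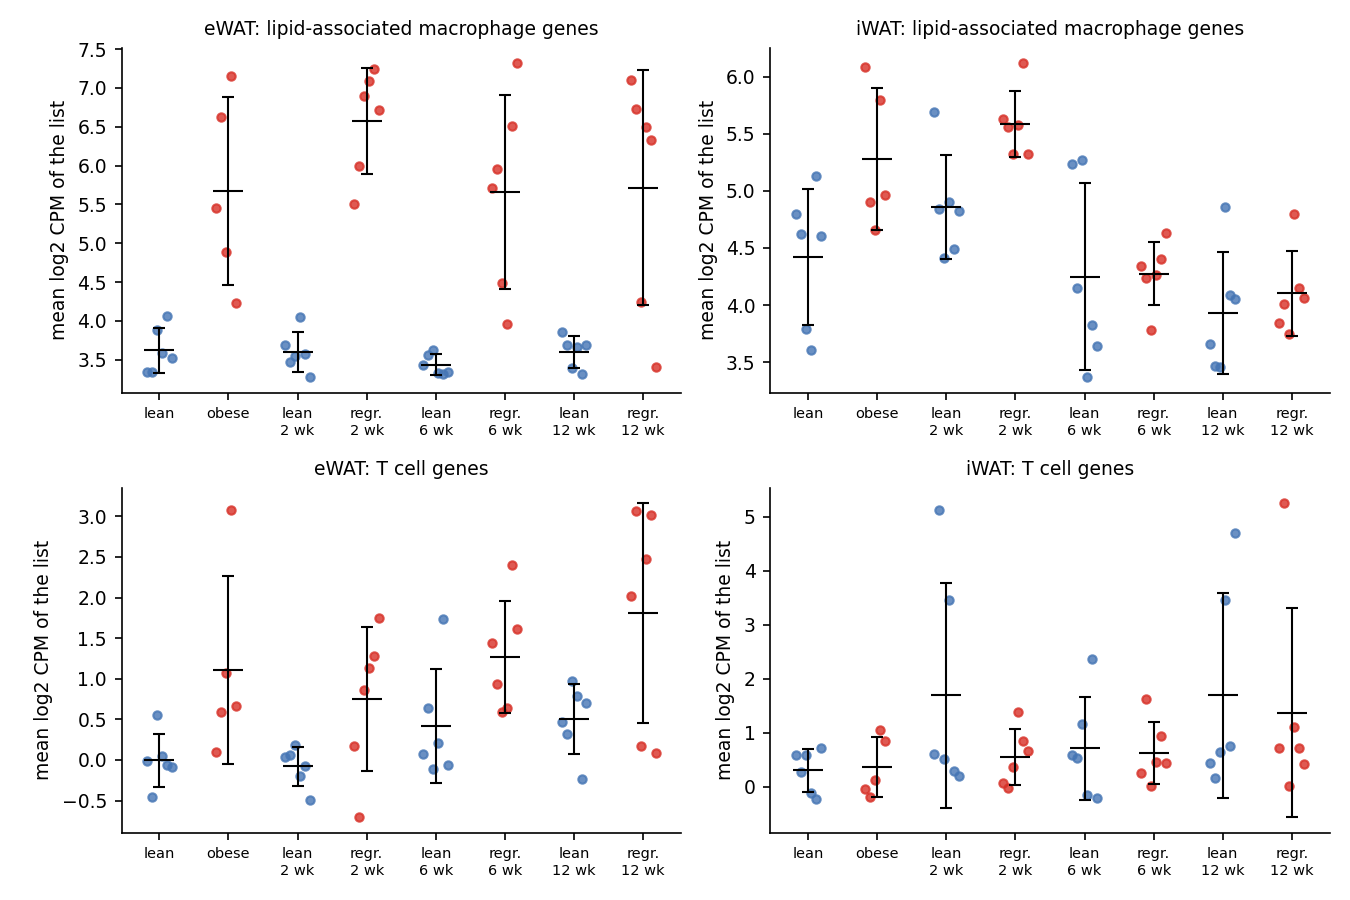
Score of the lipid-associated macrophage and T cell lists (mean log2 CPM) per library in both tissues, by group, with the mean and SD. In eWAT the lipid-associated macrophage score of the 6 regression libraries at 12 weeks ran from 3.41 to 7.10 and that of the 6 lean libraries from 3.32 to 3.86.

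498 genes were called in the same direction at all 4 times in eWAT, 483 of them higher and 15 lower, and 0 in iWAT, where edgeR called 4 genes at 12 weeks (2067 at an unadjusted p under 0.05; DESeq2 called 90). The 10 strongest in eWAT included Mmp12, Rgs1, Atp6v0d2, Tm4sf19, F7, Il1rn, Vsig8 and Tlr13. Il1rn, which encodes the antagonist of the interleukin 1 receptor, was 13.5 ± 10.6 against 0.784 ± 0.517 CPM at 12 weeks (4.11 ± 0.87, adjusted p = 0.00161). Of the 483 genes, 275 were called higher in the iWAT of obese mice and 0 at 12 weeks (8 with muscle and lymph node signals as terms). The genes were chosen by their calls in eWAT, which favours a larger difference there. The test of the difference between the tissues at 12 weeks called 3 of the 483, and 372 had an unadjusted p under 0.05. In simulation, fitted on the 12-week libraries alone, that test recovered 50.7% of 2-fold changes. The low count of calls therefore does not show that the depots responded alike. With duct and vas deferens signals as terms 155 genes were called higher at all 4 times, 151 of them among the 483.

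In iWAT at 12 weeks 3 genes were higher and 1 lower (4; 2067 at an unadjusted p under 0.05, 90 by DESeq2). Left-out libraries gave 2 to 58 for iWAT 12 weeks; the count was 1 with the run of mouse numbers as a random block and 0 by edgeR on the compared groups alone (1449 at an unadjusted p under 0.05). Cebpb, a transcription factor of adipocyte differentiation (chromosome 2, 167688915 to 167690418), was 159 ± 49.2 against 451.5 ± 182 CPM (-1.50 ± 0.25, adjusted p = 0.00219). Klf6 (chromosome 13, 5861482 to 5870394) rose by 0.79 ± 0.13, adjusted p = 0.00219, Prickle1 by 0.64 ± 0.12, adjusted p = 0.0145, and Catsperg1, named after its value was seen, by 1.12 ± 0.21, adjusted p = 0.0111. On the compared groups alone none of these calls was made, with adjusted p = 0.21 for Cebpb iWAT 12 weeks, Klf6 iWAT 12 weeks and Prickle1 iWAT 12 weeks at log2 fold changes of -1.50, 0.78 and 0.64. With the random block the adjusted p was 0.0765, 0.0475 and 0.386. Cebpb also differed among lean mice, where it was higher at 12 weeks than at the obesity time (1.06 ± 0.24, adjusted p = 0.0287). Over all genes 0 of 19 genes of the tricarboxylic acid cycle were called, but 19 adjusted over the list alone (13 over all genes with muscle and lymph node signals as terms; adjusted p = 0.211 with an estimated correlation), and for fatty acid oxidation 0 of 20 and 19 (17 with the terms; adjusted p = 0.211). Hadha (-0.77 ± 0.21) and Pdha1 (-0.64 ± 0.24) were lower by value without a call over all genes. The thermogenic list score was below that of every lean library in all 6 regression libraries (2.41 to 4.26 against 4.32 to 5.26 log2 CPM), a difference of -1.11 (exact permutation p = 0.00216, the smallest these groups allow, adjusted p = 0.0149). The fatty acid oxidation score differed by -0.57 (exact permutation p = 0.00649, adjusted p = 0.0308). Ucp1 was 13.9 ± 16.7 against 85.2 ± 63.1 CPM (-2.64 ± 0.84, adjusted p = 0.164; -3.06 ± 0.78, adjusted p = 0.029 with muscle and lymph node signals as terms). With those terms 112 genes were higher and 295 lower. The camera test called 0 of 41 lists with an estimated correlation, 11 with the preset correlation and fry called 3.

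**Figure D3:**
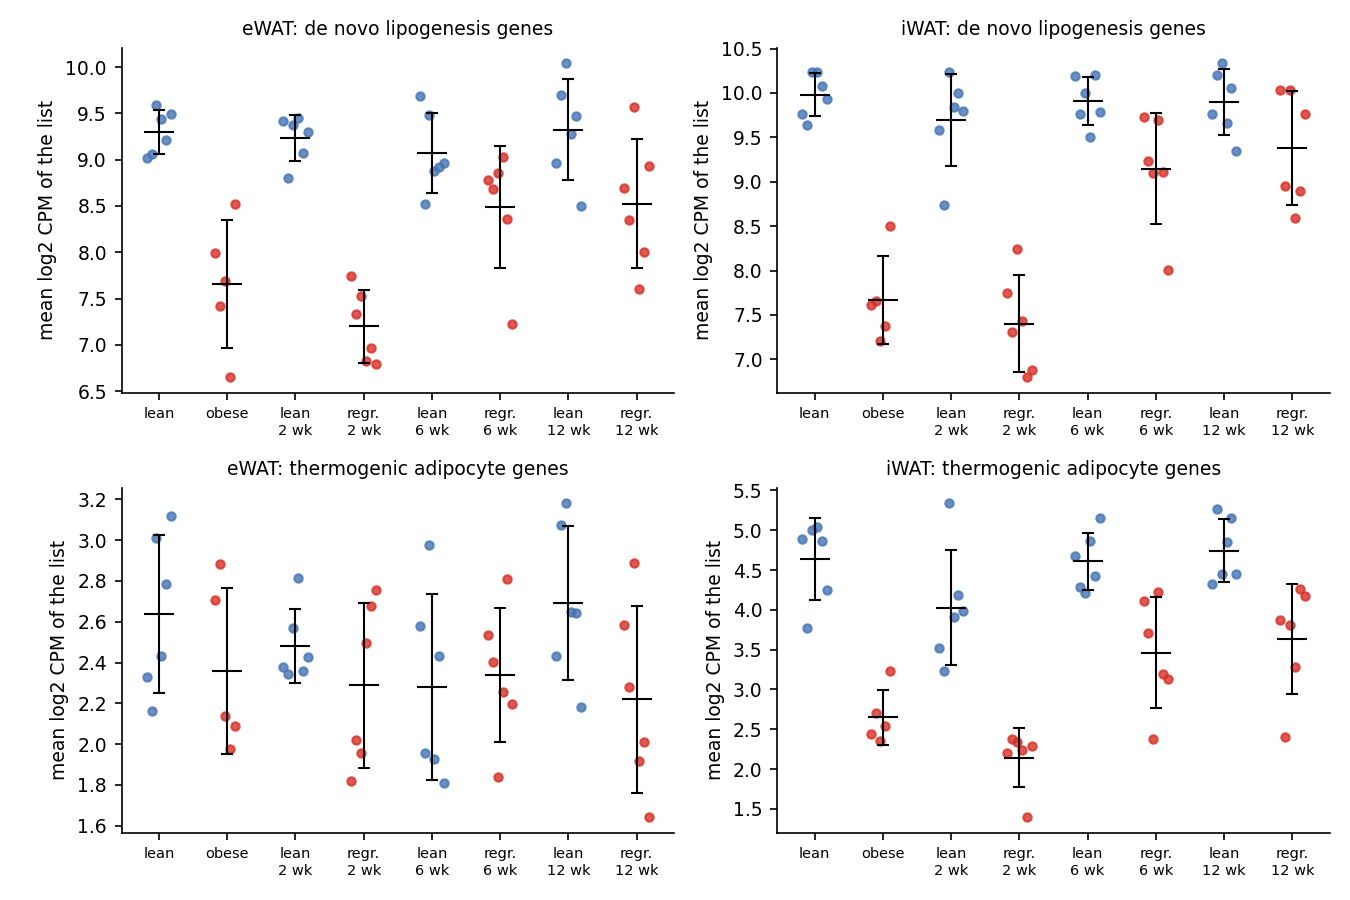
Score of the de novo lipogenesis and thermogenic lists (mean log2 CPM) per library in both tissues, by group, with the mean and SD. In iWAT at 12 weeks the thermogenic score ran from 2.41 to 4.26 in the 6 regression libraries and from 4.32 to 5.26 in the 6 lean libraries.

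The change of the difference from lean mice between obesity and a later time was tested in the same fit. In eWAT 834, 174 and 333 genes changed by 2, 6 and 12 weeks. On the compared groups alone the counts were 488, 82 and 280, and DESeq2 called 531 for eWAT change by 12 weeks. Lep fell by 2 weeks (-3.10 ± 0.40, adjusted p = 7.30e-06) and by 12 weeks (-2.44 ± 0.39, adjusted p = 0.000251). By 12 weeks Oxtr, the oxytocin receptor, fell by 3.49 ± 0.38 (adjusted p = 1.56e-07), Slc5a7 by 3.92 ± 0.58 and Trp53inp2 by 2.70 ± 0.36, while Hsd11b1, which activates glucocorticoids, rose by 2.87 ± 0.39 (adjusted p = 2.55e-05). The list of adipocyte enlargement was past its test for the change by 6 weeks (camera with an estimated correlation, adjusted p = 0.0435, lower). In iWAT 556, 192 and 674 genes changed, and 290, 624 and 512 on the compared groups alone. With the run of mouse numbers as a random block it was 151 for iWAT change by 2 weeks, 23 for iWAT change by 6 weeks and 195 for iWAT change by 12 weeks, and left-out libraries gave 289 to 914, 70 to 356 and 4.5e+02 to 886. By 12 weeks Slc2a5 rose by 6.82 ± 0.96 (adjusted p = 6.55e-05), Elovl6 by 4.77 ± 0.76, Sorcs2 by 3.90 ± 0.59 and Hsd11b1 by 2.56 ± 0.39, and Slc5a7 fell by 5.49 ± 0.91. For the change of Trem2 in eWAT by 12 weeks the adjusted p was 0.983 (0.10 ± 1.04). Among lean mice 15 genes differed between 12 weeks and the obesity time in eWAT, including Wnk3 (-1.80 ± 0.36), and 69 in iWAT, including Tnk2 (1.10 ± 0.18), Rgs16 (-2.06 ± 0.39) and the clock genes Ciart (-1.93 ± 0.39) and Bhlhe41 (-1.46 ± 0.30). Left-out libraries moved these counts from 0 (edgeR, 1363 to 1474 at an unadjusted p under 0.05) to 94 in eWAT, where 3 of 60 splits of the libraries called as many and chance was not excluded, and from 29 to 116 in iWAT. DESeq2 called 139 for eWAT lean 12 weeks and 164 for iWAT lean 12 weeks.

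Whether the depots differed in their response was tested with mouse as a block over 14749 genes. The response differed for 195 genes in obesity, 1242 at 2 weeks, 88 at 6 weeks and 8 at 12 weeks. On the compared groups alone the counts were 56, 726, 261 and 3. DESeq2 called 345 for tissue difference obesity, 335 for tissue difference 6 weeks and 637 for tissue difference 12 weeks. The mouse series of replicates 4 to 6 gave 0, 3 for tissue difference 2 weeks, 0 and 0 by edgeR (1446, 1313 and 2801 at an unadjusted p under 0.05 for the counts of 0). In obesity the fall was larger in iWAT for Sorcs2 (4.88 ± 0.91, adjusted p = 0.0021, eWAT minus iWAT), Aspg (4.55 ± 0.68), Slc2a5 (4.16 ± 0.73), Acot11 (4.03 ± 0.72) and Otop1 (3.43 ± 0.63), and Sez6l (-2.98 ± 0.77) went the other way. At 2 weeks Ucp1 (7.86 ± 1.18, adjusted p = 9.69e-05), Rgs1 (6.31 ± 1.11), Mmp12 (5.91 ± 0.92) and Il7r (4.87 ± 0.93) had the more positive response in eWAT. Ucp1 was low in eWAT (1.10 ± 1.16 against 0.113 ± 0.0655 CPM, SD) and fell in iWAT, where lean replicate 3 held 60.3% of the lean group's CPM. At 6 weeks Mmp12 (8.04 ± 1.22, adjusted p = 0.000376), Rgs1 (6.34 ± 1.20), Atp6v0d2 (5.45 ± 1.09) and Itgax (4.04 ± 0.75) did. The genes at 12 weeks included Mmp12 (6.91 ± 1.4, adjusted p = 0.0278), Itgax (4.06 ± 0.76, adjusted p = 0.0164), Clec7a (2.63 ± 0.56), Lctl (1.22 ± 0.26), Cyb5r4 (1.03 ± 0.16, adjusted p = 0.00166), Abat (-1.51 ± 0.28) and Zzz3 (-0.37 ± 0.08). The score of the lipid-associated macrophage list, taken as eWAT minus iWAT in each mouse, differed from lean by 1.19 in obesity (exact permutation p = 0.0584, adjusted p = 0.109 over 28 tests), 2.24 at 2 weeks (exact permutation p = 0.00216, adjusted p = 0.0302), 2.19 at 6 weeks (exact permutation p = 0.00649, adjusted p = 0.0363) and 1.94 at 12 weeks (exact permutation p = 0.0216, adjusted p = 0.055). The thermogenic score of lean mice at the obesity time was lower in eWAT than in iWAT (-2.25 ± 0.58, SD). Whether a floor in eWAT limited its fall there was not tested. For the thermogenic score the differences from lean were 1.75 in obesity (exact permutation p = 0.00433, adjusted p = 0.0303), 1.78 at 2 weeks (exact permutation p = 0.00216, adjusted p = 0.0302), 1.24 at 6 weeks (exact permutation p = 0.0152, adjusted p = 0.0532) and 0.69 at 12 weeks (exact permutation p = 0.119, adjusted p = 0.196). For de novo lipogenesis they were 0.56, 0.05, 0.18 and -0.04 (exact permutation p = 0.0216, 0.797, 0.277 and 0.81, adjusted p = 0.055, 0.871, 0.408 and 0.871).

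**Figure D4:**
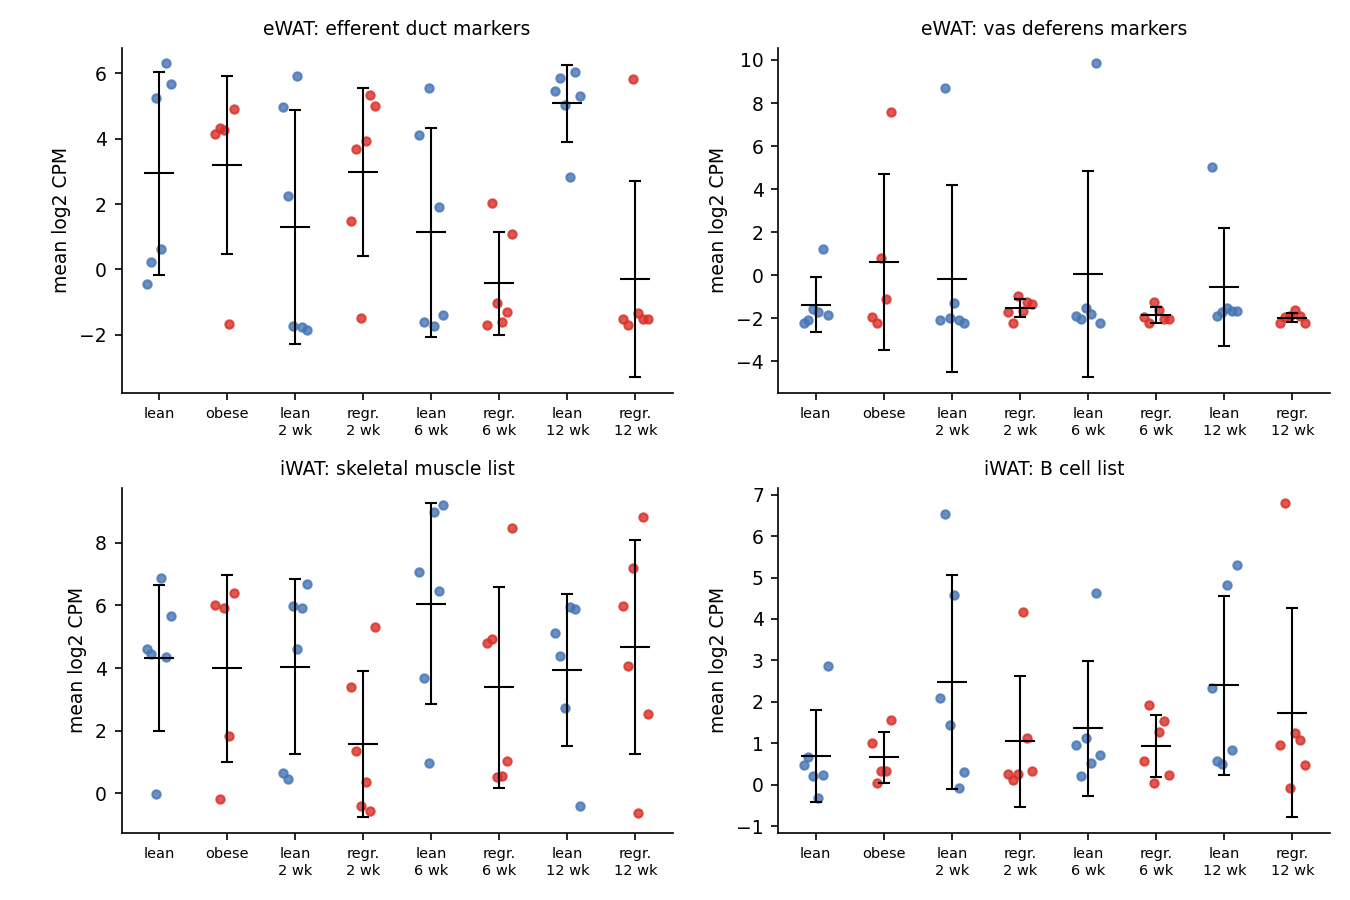
Signals of other tissues (mean log2 CPM of marker genes) per library, by group: efferent duct and vas deferens in eWAT, skeletal muscle and B cells in iWAT. The duct signal was at least 2 in 6 of 6 lean and 1 of 6 regression eWAT libraries at 12 weeks.

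The authors' deposited table called 3818, 5328, 1466 and 2749 genes in eWAT at the 4 times, of which 3330, 4939, 1049 and 2191 were called in the same direction by edgeR here. In iWAT it called 4427, 2870, 4.4e+02 and 90 genes, of which 4171, 2550, 142 and 3 were shared. A DESeq2 refit of the counts called 3846, 5369, 1465 and 2766 genes in eWAT and 4453, 2894, 4.3e+02 and 90 in iWAT.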

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

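The signals of duct, vas deferens, muscle and lymph node and the tests that use them, and the tests of list scores, were chosen after the data had been seen, apart from that of adipocyte share; the tests of adipocyte share and power and the fits of differences between depots and times were planned. A library was set apart where its distance to the nearest other library of its group, divided by the range of the group, was above Dixon's 95% critical value for the group's size. 18 of 144 groups of values held such a library; chance gives about 1 in 20 groups, here 7.2.

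In eWAT the vas deferens signal stood far above the other libraries of its group in lean replicate 5 of the obesity time (1.22 log2 CPM, others -2.22 to -1.57), lean replicate 2 at 2 weeks (8.69, others -2.22 to -1.28), lean replicate 5 at 6 weeks (9.84, others -2.22 to -1.53) and lean replicate 1 at 12 weeks (5.04, others -1.91 to -1.51). The duct signal was low in obese replicate 4 (-1.66, others 4.14 to 4.91) and in lean replicate 4 at 12 weeks (2.82, others 5.02 to 6.04), and high in regression replicate 3 at 12 weeks (5.83, others -1.70 to -1.33). Regression replicate 5 at 12 weeks held 25.9 M counts (others 6.65 to 13.2 M).

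In iWAT the muscle signal of lean replicate 3 at the obesity time was low (-0.01 log2 CPM, others 4.35 to 6.89). The lymph node signal, the mean of B cell genes, was high in lean replicate 6 of the obesity time (2.86, others -0.31 to 0.66), regression replicate 4 at 2 weeks (4.17, others 0.12 to 1.13), lean replicate 5 at 6 weeks (4.62, others 0.21 to 1.13) and regression replicate 2 at 12 weeks (6.79, others -0.08 to 1.24), where the T cell score was also high (5.25, others 0.01 to 1.11). Regression replicate 1 at 2 weeks held 34.3 M counts (others 7.76 to 13.4 M). Regression replicate 5 at 2 weeks had the highest macrophage score of its group (7.62, others 6.31 to 6.77) and the lowest thermogenic score (1.40, others 2.20 to 2.38). The de novo lipogenesis score of regression replicate 6 at 6 weeks was low (8.01, others 9.10 to 9.73).

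The response differed between the depots, by the test of that difference, for 195 genes in obesity, 1242 at 2 weeks, 88 at 6 weeks and 8 at 12 weeks, led at the last time by Cyb5r4, Itgax and Mmp12. Fitted on the compared groups alone the counts were 56, 726, 261 and 3, against a highest of 0 among the other splits at each time. The share of 1 of 25 is the lowest that 25 splits can give, and it was not adjusted over the 4 times. Fitted apart, the series of replicates 4 to 6 gave 0 by edgeR in obesity and at 6 and 12 weeks (1446, 1313 and 2801 at an unadjusted p under 0.05). At 12 weeks the other series also gave 0 (1093 unadjusted), while the remaining series counts were above 0. The share was thus under the limit set for excluding chance only barely, and as far as single mice are exchanged. At 12 weeks, with 3 genes against 0 and both series at 0, the comparison decides little. The difference from lean mice changed between obesity and 2, 6 and 12 weeks for 834, 174 and 333 genes in eWAT, Lep and Oxtr among them, and for 556, 192 and 674 in iWAT, with Elovl6 and Slc2a5. On the compared groups alone iWAT gave 290, 624 and 512 genes against a highest of 0, 1 and 4 in other splits (1 of 60 each), and chance was excluded as far as single mice are exchanged. These splits leave aside the runs of mouse numbers, and with the run as a random block the iWAT counts were lower. In eWAT 488 and 280 genes were called by 2 and 12 weeks (2 of 60 splits as large at each) and 82 by 6 weeks (3 of 60, chance not excluded). By 2 and 12 weeks the share was under the limit set for excluding chance, as far as single mice are exchanged. That verdict is weak, since other splits reached 1462, 658 and 1078 genes, above the real count each time. Whether this reflects a structure among the eWAT libraries besides the groups was not tested. The mouse series fitted apart, with fewer libraries each, gave lower counts. Between lean mice at 12 weeks and at the obesity time 47 genes were called in iWAT (highest other 1, 1 of 60, chance excluded with the same limit) and 10 in eWAT (highest other 552, with a duct gap of 3.50, 3 of 60, chance not excluded).

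The first pattern is the high macrophage and T cell genes of eWAT after 12 weeks, set beside the duct signal that 6 of 6 lean and 1 of 6 regression libraries held. Slopes on the duct and vas deferens signals together were taken from the 6 other groups. They predicted 4.21% of the median log2 fold change of 2.25 of the 40 called genes of the macrophage, lipid-associated macrophage and T cell lists (0 of 40 by at least 50%). The T cell list was not taken by itself. Over the 1549 higher genes they predicted 9.52% (34) and over the 646 lower genes 8.46% (137). The slopes argue against duct and vas deferens reads as the source of most of the median fold of each set, though the predictions have no interval. They do not decide this for the 137 lower genes predicted by at least 50%. Nor do they decide it for T cell genes by themselves. With duct and vas deferens as terms 0 of 15 T cell genes were called, against 15 of 18 macrophage genes. A lower share of adipocytes would raise macrophage and endothelium genes alike, but the gap between their scores was 1.95 larger in regression mice (-0.11 ± 1.08 against -2.06 ± 0.31, SD, exact permutation p = 0.00433). With duct and vas deferens as terms the median fold of the higher genes was 0.70 in place of 0.86 and its SE 0.25 in place of 0.23, and 281 in place of 1549 genes were called; whether the terms took up a duct-related part or part of the difference between the groups was not tested. What stays open is a cause tied to both, such as the part of the depot taken, and the diet history of the mice, a hypothesis; regression replicate 3, with duct signal, and replicate 6, without it, had the lowest lipid-associated macrophage scores (4.24 and 3.41, others 6.33 to 7.10).

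The second pattern is the low number of iWAT calls after 12 weeks, 4 genes by edgeR (2067 at an unadjusted p under 0.05; 90 by DESeq2). With muscle and lymph node signals as terms 112 genes were higher and 295 lower (4.1e+02 in all, Ucp1 among the lower), so varying muscle and lymph node in the libraries could account for part of the low count. Of simulated 2-fold changes at these groups 80.6% were recovered (exact 95% interval 69.1% to 89.2%), which does not settle whether power for 2-fold changes reached 80%. The thermogenic score was lower by 1.11 (exact permutation p = 0.00216, adjusted p = 0.0149) and the fatty acid oxidation score by 0.57 (exact permutation p = 0.00649, adjusted p = 0.0308). With the terms 17 of 20 genes of the latter list were lower. As far as single mice are exchanged, these values argue against a full return of the tissue to the lean state, while a partial return stays open. The permutations leave aside the runs of mouse numbers, and camera with an estimated correlation called 0 of 41 lists.

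The third pattern is the set of genes that fell most in eWAT at 2 and 6 weeks, Akr1b7, Crisp1, Serpina1f, Spink8, Ptgs2 and Defb42. A single lean library held a median of 100% of the lean group's CPM over these genes, replicate 2 at 2 weeks and replicate 5 at 6 weeks. The vas deferens signal is the mean of 4 of these genes, so its height in the same libraries is no separate evidence. These genes are made in the epithelium of the vas deferens and epididymis, which lie against this depot, so vas deferens tissue in 1 lean library is consistent with the fall, while the tissue itself was not identified from other genes and no biological explanation was tested.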

How the results depend on the processing

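Fits with signals of other tissues as terms, fits that leave out libraries for their depth, duct or lymph node signal, and the replicate block with the preset correlation were chosen after the results were seen; the other tests in this part were planned. Counts are of genes called, listed where they moved by over 1.5 times; beside each alternative stands the number of results it left within that range. The cause of a move was not tested unless one is given. Without a count filter and with RLE size factors the 20 counts of genes each stayed within 1.5 times. The library with the fewest counts, at 1.32 M in regression replicate 2 at 2 weeks, limits what is seen of weak genes there; without it eWAT lean 12 weeks was 68, and 7 counts were within range. Leaving out 1 library at a time was not run for the tissue difference, the kept calls or the lists.

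DESeq2 gave tissue difference obesity 345, tissue difference 6 weeks 335, tissue difference 12 weeks 637, eWAT change by 12 weeks 531, eWAT lean 12 weeks 139, iWAT 6 weeks 4.3e+02, iWAT 12 weeks 90, iWAT change by 2 weeks 886, iWAT change by 6 weeks 4.2e+02, iWAT lean 12 weeks 164, iWAT obesity calls kept at 6 weeks 283 and iWAT obesity calls kept at 12 weeks 52; 14 were within range.

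The mouse series fitted apart use fewer libraries each. The series of replicates 4 to 6 gave tissue difference obesity 0, tissue difference 2 weeks 3, tissue difference 6 weeks 0 and tissue difference 12 weeks 0 (1446, 1313 and 2801 for the counts of 0 at an unadjusted p under 0.05 by edgeR), eWAT obesity 1513, eWAT 6 weeks 0 (2542 unadjusted), eWAT 12 weeks 1, eWAT change by 2 weeks 93, eWAT change by 6 weeks 7, eWAT change by 12 weeks 71, eWAT lean 12 weeks 0 (899 unadjusted), iWAT obesity 1327, iWAT 6 weeks 5, iWAT change by 2 weeks 55, iWAT change by 6 weeks 10, iWAT change by 12 weeks 148 and iWAT lean 12 weeks 24; 3 were within range. The series of replicates 1 to 3 gave tissue difference obesity 13, tissue difference 2 weeks 282, tissue difference 6 weeks 4, tissue difference 12 weeks 0 (1093 unadjusted), eWAT obesity 607, eWAT 2 weeks 2108, eWAT 6 weeks 0 (1908 unadjusted), eWAT 12 weeks 672, eWAT change by 2 weeks 187, eWAT change by 6 weeks 15, eWAT change by 12 weeks 22, eWAT lean 12 weeks 2, iWAT obesity 2583, iWAT 2 weeks 700, iWAT 6 weeks 3, iWAT 12 weeks 7, iWAT change by 6 weeks 0 (2132 unadjusted), iWAT change by 12 weeks 47 and iWAT lean 12 weeks 15; 1 was within range. DESeq2 was not run on the series. With the series as a term eWAT lean 12 weeks was 27 and iWAT 12 weeks 9, and 14 were within range.

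With the replicate number as a replicate block eWAT change by 6 weeks was 105 and iWAT obesity calls kept at 12 weeks 1, and 30 counts, of lists and genes, were within range. Same-numbered libraries of different groups had mean correlations of -0.0305 in eWAT and 0.0148 in iWAT (64 and 70 of 161 pairs over 0.1), and 6 and 5 of 47 libraries correlated best with their own number. For the depots of a mouse the mean was 0.238; with no replicate block for the mouse tissue difference obesity was 36, tissue difference 2 weeks 590 and tissue difference 12 weeks 17, and tissue difference 6 weeks was within range. With the run of neighbouring mouse numbers as a random block in limma (correlation 0.0667 in eWAT, 0.123 in iWAT) eWAT 6 weeks was 23, eWAT change by 2 weeks 488, eWAT change by 6 weeks 54, eWAT lean 12 weeks 1, iWAT 2 weeks 1219, iWAT 6 weeks 31, iWAT 12 weeks 1, iWAT change by 2 weeks 151, iWAT change by 6 weeks 23, iWAT change by 12 weeks 195 and iWAT lean 12 weeks 13; 5 were within range.

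On the compared groups alone eWAT change by 2 weeks was 488, eWAT change by 6 weeks 82, iWAT 2 weeks 1347, iWAT 6 weeks 376, iWAT 12 weeks 0 (1449 unadjusted by edgeR), iWAT change by 2 weeks 290 and iWAT change by 6 weeks 624; 9 were within range. With signals of other tissues as terms eWAT 12 weeks was 4.0e+02, iWAT 6 weeks 274, iWAT 12 weeks 4.1e+02, iWAT change by 6 weeks 4.1e+02, iWAT lean 12 weeks 130, eWAT obesity calls kept at 12 weeks 224, iWAT obesity calls kept at 6 weeks 209 and iWAT obesity calls kept at 12 weeks 265; 14 were within range. From libraries with duct signal alone eWAT obesity was 901, and from those without it eWAT 2 weeks was 1240 and eWAT 6 weeks 16, with fewer libraries in each. Without libraries with a lymph node signal iWAT 12 weeks was 15, iWAT change by 2 weeks 317, iWAT change by 6 weeks 341, iWAT change by 12 weeks 4.1e+02 and iWAT lean 12 weeks 21; 3 were within range. Calls of at least 2-fold at both times were fewer, with eWAT obesity calls kept at 2 weeks 680, eWAT obesity calls kept at 6 weeks 337, eWAT obesity calls kept at 12 weeks 518, iWAT obesity calls kept at 2 weeks 261 and iWAT obesity calls kept at 6 weeks 31.

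For gene lists camera with the preset correlation, fry, and the replicate block with the preset correlation called 22, 18 and 24 in gene lists eWAT obesity, 22, 25 and 22 in gene lists eWAT 2 weeks, 22, 4 and 22 in gene lists eWAT 6 weeks, 26, 23 and 26 in gene lists eWAT 12 weeks and 7, 2 and 8 in gene lists eWAT change by 12 weeks. The counts were 21, 23 and 20 in gene lists iWAT obesity, 25, 17 and 25 in gene lists iWAT 2 weeks, 16, 0 and 16 in gene lists iWAT 6 weeks, 11, 3 and 11 in gene lists iWAT 12 weeks and 19, 6 and 19 in gene lists iWAT change by 12 weeks. The preset correlation is lower than the correlation within most lists, and fry does not compare a list with other genes.

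Leaving out 1 library at a time gave eWAT obesity 1722 (without obese replicate 4) to 3560, eWAT 2 weeks 4474 to 5450, eWAT change by 2 weeks 577 to 1103, eWAT change by 12 weeks 235 to 390, iWAT obesity 3372 to 4298 and iWAT 2 weeks 1779 to 2791. For eWAT 6 weeks it was 178 to 1585, with 178 without regression replicate 6, 583 without replicate 5 and 664 without lean replicate 3. For eWAT 12 weeks it was 1280 to 4253: 4253 without regression replicate 3, 1395, 1280 and 1374 without replicates 2, 4 and 5, and 1403 without lean replicate 2. For eWAT change by 6 weeks it was 96 (without lean replicate 6 of the obesity time) to 212, with 111 without lean replicate 5 and 115 without regression replicate 1 of 6 weeks. For eWAT lean 12 weeks it was 0 to 94: without 12-week replicates 1, 3 and 5 it was 0, 0 and 35 (1474 and 1447 unadjusted for the counts of 0), and without replicates 1 to 6 of the obesity time 0, 0, 94, 2, 58 and 3 (1363 and 1440 unadjusted).

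In iWAT 6 weeks the range was 55 to 330: 69, 221, 88 and 64 without lean replicates 1, 2, 5 and 6, and 217, 82, 55, 330, 68 and 253 without regression replicates 1 to 6. For iWAT 12 weeks it was 2 to 58: 2 and 58 without lean replicates 3 and 6, 14 and 2 without regression replicates 2 and 4. For iWAT change by 2 weeks it was 289 to 914: 370 without lean replicate 1 of 2 weeks, 340, 353 and 914 without regression replicates 1, 3 and 5, 352 without lean replicate 4 of the obesity time and 289 without obese replicate 4. For iWAT change by 6 weeks it was 70 to 356: 124 and 126 without lean replicates 2 and 4 of 6 weeks, 114, 122, 114 and 301 without regression replicates 1, 2, 4 and 6, 117 and 115 without lean replicates 4 and 6 of the obesity time, and 117, 96, 70 and 356 without obese replicates 1, 2, 4 and 5. For iWAT change by 12 weeks it was 4.5e+02 (without obese replicate 1) to 886. For iWAT lean 12 weeks it was 29 to 116: 35, 30, 35 and 116 without 12-week replicates 1, 3, 5 and 6, and 29, 39, 36 and 37 without replicates 1, 2, 4 and 6 of the obesity time.

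Of 358 log2 fold changes of named genes (223 called), 3347 of 3853 values under alternatives had the same direction and side of the threshold, 31 were newly called, 16 had the other sign or a value of 0 and the rest were no longer called. Of these 16, with the duct and vas deferens signals as terms there were Crisp1 eWAT obesity at -0.37, Akr1b7 eWAT 2 weeks at 0.90, Serpina1f eWAT 2 weeks at 1.41, Ptgs2 eWAT 2 weeks at 0.0097, Serpina1f eWAT 6 weeks at 1.71, Crisp1 eWAT 6 weeks at 0.0197 and Defb42 eWAT 6 weeks at 0.24, where the vas term is itself the mean of Akr1b7, Crisp1, Serpina1f and Defb42. In the series of replicates 4 to 6 they were Akr1b7 eWAT 2 weeks at 3.56, Crisp1 eWAT 2 weeks at 0.65, Serpina1f eWAT 2 weeks at 0, Akr1b7 tissue difference 2 weeks at 1.52 and Saa3 iWAT obesity at -0.29, and in that of replicates 1 to 3 Cd8a eWAT 2 weeks at -0.0265 and Akr1b7 eWAT 6 weeks at 1.4. Without lymph node libraries they were Cd3e iWAT 2 weeks at 0.18 and Cd8a iWAT 2 weeks at 0.0268.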

Other observations

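The comparisons and lists in this part were planned, except the test of the difference signed by its direction in obesity, which was chosen after the result was seen, as were the genes named as examples. Of the clock genes, those lower in obese mice included Ciart (-1.83 ± 0.42, adjusted p = 0.00151 in eWAT, -2.05 ± 0.41, adjusted p = 0.000223 in iWAT), Bhlhe41 (-1.37 ± 0.28 and -1.83 ± 0.32) and Dbp (-1.09 ± 0.30 and -1.17 ± 0.33). Of the circadian clock list 6 of 16 genes fell in eWAT (6 adjusted over the list alone; adjusted p = 0.361 with an estimated correlation) and 7 of 16 in iWAT (7; adjusted p = 0.470), while 1 of 16 rose in each. The hour at which the mice were killed is not given in the sources used here. Among immediate early genes at 2 weeks of the low-fat diet, Fos rose by 2.12 ± 0.51, adjusted p = 0.00112 in eWAT and 2.51 ± 0.57, adjusted p = 0.00185 in iWAT and Hspa1a, a heat shock gene, by 1.5 ± 0.41 and 1.77 ± 0.61; 8 of 13 list members rose in eWAT (8 adjusted over the list alone; adjusted p = 0.548 with an estimated correlation) and 7 of 13 in iWAT (10; adjusted p = 0.475). Klf6, called in iWAT after 12 weeks, was also higher in eWAT at 2 weeks (0.75 ± 0.15) and 12 weeks (0.74 ± 0.15); with duct and vas deferens signals as terms the call at 12 weeks was lost (0.53 ± 0.16, adjusted p = 0.0542).

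Pdgfra, a receptor of adipose progenitor cells, was higher in eWAT at all 4 times (0.82 ± 0.24, 1.28 ± 0.23, 1.14 ± 0.23 and 1.22 ± 0.23, adjusted p = 0.000812 at 12 weeks) and in the iWAT of obese mice (0.67 ± 0.22), where Pi16 rose by 1.34 ± 0.26 and 11 of 16 progenitor genes were higher (12 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation). Cdkn2a, which encodes inhibitors of the cell cycle, rose in eWAT in obesity (1.42 ± 0.41) and was higher at 6 (1.35 ± 0.41) and 12 weeks (1.10 ± 0.39, adjusted p = 0.0489; 0 of 11 genes of its list were called at 12 weeks with duct and vas deferens signals as terms); Cdkn1a rose in obesity (1.66 ± 0.34, adjusted p = 0.000532) and had no call at the later times. After 12 weeks 6 of 10 mast cell genes were higher in eWAT (6 adjusted over the list alone, 4 with duct and vas deferens signals as terms; adjusted p = 0.401 with an estimated correlation), among them Ms4a2 (1.78 ± 0.49) and Tpsb2 (1.5 ± 0.40), and 6 of 12 B cell genes (10, 0 with the terms; adjusted p = 0.401). Of the skeletal muscle genes 3 of 14 fell in iWAT at 2 weeks (3, 0 with muscle and lymph node signals as terms; adjusted p = 0.697). At 2 weeks 11 of 21 interferon genes were higher in eWAT (13 adjusted over the list alone; adjusted p = 0.548 with an estimated correlation), Irf7 by 0.45 ± 0.16. Oxtr was higher in the eWAT of obese mice (2.20 ± 0.27) and lower after 12 weeks (-1.29 ± 0.26, adjusted p = 0.00118).

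A hypothesis tested here is that the genes called in obese mice still deviate a little in the same direction where few are called singly. The mean difference of these genes from lean mice, signed by their direction in obesity, was 0.66, 0.45 and 0.47 log2 units in eWAT at 2, 6 and 12 weeks (exact permutation p = 0.00216, 0.00649 and 0.026). In iWAT it was 0.35 and 0.26 at 2 and 6 weeks (exact permutation p = 0.00866 and 0.00216) and 0.19 at 12 weeks, with 80.1% of the 4195 genes on the side they took in obesity. The exact permutation p of the last was 0.0541 (adjusted p = 0.0541 over 6 tests), so whether iWAT holds a residue of the obesity difference after 12 weeks was not decided.

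Counts of calls were also set beside those of other splits of the same libraries, each fitted on the compared groups alone, with the real groups counted among 100 splits. In eWAT the real groups gave 2325 genes in obesity (highest other split 1193), 3811 at 2 weeks (2749) and 988 at 6 weeks (879), each 1 of 100, and chance was excluded as far as single mice are exchanged. The splits leave aside the runs of mouse numbers and the mouse series: for eWAT 6 weeks the run as a random block left 23 genes, and the series fitted apart 0 and 0 by edgeR (2542 and 1908 at an unadjusted p under 0.05). At 12 weeks 1616 genes were called and 2 of 100 splits gave as many, so chance was excluded too with the same limit, but another split reached 3.8e+03. By its duct signals, that split was the real grouping with lean replicate 4 (2.82 log2 CPM) and regression replicate 3 (5.83) exchanged and the sides switched. The gap in duct signal between its sides was 6.38 log2 CPM, where regression minus lean was -5.37. Since most libraries stayed with their own group, this split cannot tell duct signal from diet. In iWAT 4373 genes in obesity (3143), 1347 at 2 weeks (3) and 376 at 6 weeks (205) were each 1 of 100, and chance was excluded with the same limit. At 12 weeks edgeR called 0 genes on the compared groups alone (1449 at an unadjusted p under 0.05), and over all libraries edgeR called 4 and DESeq2 90. With a real count of 0 each of the 100 splits gives as many by construction, so the comparison decides nothing there. The highest split gave 1896, and the cause of this was not tested.

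Of the obesity calls, 1264, 545 and 641 were called again in eWAT at 2, 6 and 12 weeks and 728 and 255 in iWAT at 2 and 6 weeks on the compared groups alone. Other splits gave at most 0 (1 of 100 each), but at least 50% of the splits call no gene at each time, which nearly fixes their overlap at 0, so this comparison decides little. In iWAT at 12 weeks 0 were called again by edgeR, so 100 of 100 splits gave as many by construction. For the lists, camera with an estimated correlation called 0 for obesity, 2, 6 and 12 weeks and the change by 12 weeks in either depot on the compared groups alone. With a real count of 0 each of the 40 splits gives as many by construction (40 of 40), so the comparison decides nothing; the highest gave 1 list for iWAT at 2 weeks and for the eWAT change by 12 weeks and 0 for the others. The list called for the eWAT change by 6 weeks was not set beside splits. Among 96 pairs of a gene and a comparison that the rule for naming genes took by the size of the change, 13 had over 90% of a group's CPM in 1 library. A gene can enter at several times, as Akr1b7 and Crisp1 did.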
